A study of Mus musculus with 2 samples.

How the data were processed

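Poly(A)-selected RNA of primary microglia was sequenced as 2 libraries, 1 labelled control vector and 1 labelled Per2-overexpression vector. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was isolated with oligo(dT) beads and fragmented, cDNA was primed with random hexamers, and adapter-ligated fragments were size-selected on beads before PCR. The protocol names no step that marks the strand, so overlapping sense and antisense genes cannot be told apart in these values.

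The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 per gene and library, in a single table. HISAT2, StringTie, DESeq2 and edgeR are named without versions in the submitters' processing notes, as is the rat genome build Rnor_6.0. Their order, parameters and read filters are not given in the sources used here. The table held 26607 rows, of which 22050 carried rat Ensembl gene identifiers, each with a symbol or a placeholder name, and 4557 were loci named NewGene with no other symbol. The labels give the organism as mouse, while the build and the gene identifiers are rat. This disagreement could not be settled from the table. If the reads were from mouse, alignment to the rat genome could lower the values of diverged genes in both libraries. The reference annotation at hand was of mouse, so no genomic coordinates are given.

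FPKM values are not counts, and depth was not recoverable from them. Among 1286 genes with values above 0 and below 0.3 FPKM in both libraries, the most frequent ratio between the libraries (to 3 decimals) was shared by only 6 genes, so no common step of 1 read was found. Counting intervals and floors are therefore not given, and the depth of the libraries is unknown. FPKM summed to 659696 in the control-labelled library and to 760286 in the overexpression-labelled library.

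The columns were assigned to samples by the library names in the sample descriptions. For each gene, the log2 ratio was log2((FPKM labelled overexpression + 1)/(FPKM labelled control + 1)), a scale on which the difference of low genes is understated. Genes with a mean of at least 1 FPKM over both libraries were compared (12369 rows). With 1 library per group no test between the groups was possible and no p-value is given. A fixed rule of size, a log2 ratio of at least 1 or at most -1 (2-fold), took its place. Counts of genes at least or past 2-fold use this rule on FPKM + 1. Low genes can differ by more than 2-fold in the deposited values and not be counted. The libraries have no replicates, so no value carries an SD and the ratios describe these 2 libraries only.

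Gene lists (39, covering pathways, RNA quality and markers of cell types the cultures could hold) and the rule for named genes were fixed before the data were examined. Named genes were the members of the clock list, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with a mean of at least 5 FPKM and a symbol that is not a placeholder, up to 4 members of each list with the largest absolute log2 ratio, and 12 textbook ferroptosis and microglia genes. Values of 4 of these genes are not reported here, although those past the expression filter count in the lists. Loci whose symbol starts with NEWGENE were treated as placeholders after the ranking had been seen, which left the 12 highest and the 12 lowest genes as they were. Where 2 rows shared a symbol (107 symbols were shared), the row with the higher mean stood for the gene. Each list with at least 5 measured members was described by its median log2 ratio and by the number of 10000 random lists, of the same size and matched on mean expression in 20 bins, with a median as low or as high. Per2 was also set beside genes within 0.5 of its log2 length and within 1 of its log2 mean expression. List members are co-regulated, so these numbers are descriptions, not p-values.

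A correction for transcript length was added after the data had been seen. The length of the longest protein-coding transcript of the mouse gene with the same symbol (GENCODE M21) stood in for the rat transcript. A length was found for 96.6% of annotated genes with a symbol that is not a placeholder and for 10161 of the 12369 genes (82.1%). Length-adjusted log2 ratios are residuals from a lowess fit on log2 length with a span of 0.3, and length-matched random lists were drawn from 10 bins of expression by 10 bins of length among genes with a length. The fit carries the general level as well as the trend, so the adjustment also recentres the ratios. Their median was -0.0058 after it, against -0.18 for all genes compared. Values given with the length trend removed therefore mix both changes. Rank correlations are Spearman's, across genes, which are not independent replicates.

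Alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, rescaling to TPM (each library to a sum of 1000000), and centring on the median log2 ratio of genes with a mean of at least 5 FPKM. Removal of the length trend and restriction to annotated genes were added later. The programs were tested on simulated pairs of libraries with an assumed log2 spread of 0.3 over 12369 genes. Among 200 genes changed by a known fold, the rule counted 22.5% of 2-fold, 86.0% of 3-fold and 97.5% of 4-fold changes in the right direction, and it counted at most 0.03% of unchanged genes. The log2 ratios of the libraries at hand had an SD of 0.57 across genes, or 0.45 with the length trend removed. Both are wider than assumed and the simulated folds held no length trend, so these rates need not hold for the libraries. Of 400 unshifted lists of 20 genes, 5.2% lay outside the central 95% of random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.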

Results

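The transcriptomes of 2 cultures of primary microglia, the resident macrophages of the central nervous system, were compared. The first library was labelled as transfected with a control vector and the second as transfected with a vector for overexpression of Per2, a repressor of the circadian clock. The series concerns Per2 and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, after spinal cord injury, and the comparison addresses which transcripts of these cultures differ between the labels. Each group held 1 library, so no difference below has a replicate check and no test between groups was possible. The table listed 12619 rows at 1 FPKM or more in the control-labelled library and 11908 in the overexpression-labelled library. The depth of the libraries is unknown.

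Per2 transcript went against the labels. Per2 (ENSRNOG00000020254) stood at 6.90 FPKM in the library labelled control and at 0.927 FPKM in the library labelled Per2 overexpression, a log2 ratio of -2.04. The ratio of the deposited values was 7.44 in favour of the control-labelled library. Of 1237 genes with a similar transcript length and mean expression, 5 had a log2 ratio as low, and their median was -0.44. The directions given below therefore refer to the libraries as labelled and not to a measured gain of Per2 transcript.

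Other clock genes were also mostly lower in the overexpression-labelled library. Of 19 measured members of the circadian clock list, 3 were at least 2-fold lower, 0 were at least 2-fold higher and 16 lay between. Besides Per2 these were Bhlhe41 (9.89 against 3.97 FPKM, control-labelled value first here and throughout) and Bhlhe40 (8.01 against 3.47), which encode repressors of CLOCK-BMAL1. With the trend with transcript length removed, only Per2 of these 3 was past 2-fold (Bhlhe41 -0.69, Bhlhe40 -0.76). Cry1, a partner of PER2 in the repressor complex, had 6.39 against 3.28 FPKM, and Nr1d1, which encodes REV-ERB alpha, had 6.93 against 4.27. Clock had 4.03 against 2.07 FPKM, while Arntl, which encodes BMAL1, had 8.54 against 7.65. Per1 (4.42 against 3.31), Cry2 (4.73 against 3.65), Nr1d2 (4.60 against 3.54), Tef (5.90 against 5.23), Npas2 (1.34 against 1.00), Ciart (1.44 against 1.29), Csnk1d (39.5 against 35.8) and Csnk1e (14.2 against 13.9) differed by less than 2-fold. Dbp, an output gene of the clock, had 20.4 against 26.2 FPKM, Nfil3 had 19.4 against 24.3 and Rora had 1.36 against 2.01. Per3 (0.826 against 0.377) and Hlf (0.183 against 0.0455) were under the expression filter. The median log2 ratio of the list was -0.30. Among 10000 random lists of the same size matched on expression, 3326 had a median as low, and 5426 did when length was matched too, so the list did not stand apart from other genes. Its median had the opposite sign (0.061) once the trend with transcript length was removed. That step also recentres the ratios, and median-of-ratios centring alone gave -0.19.

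**Figure D1:**
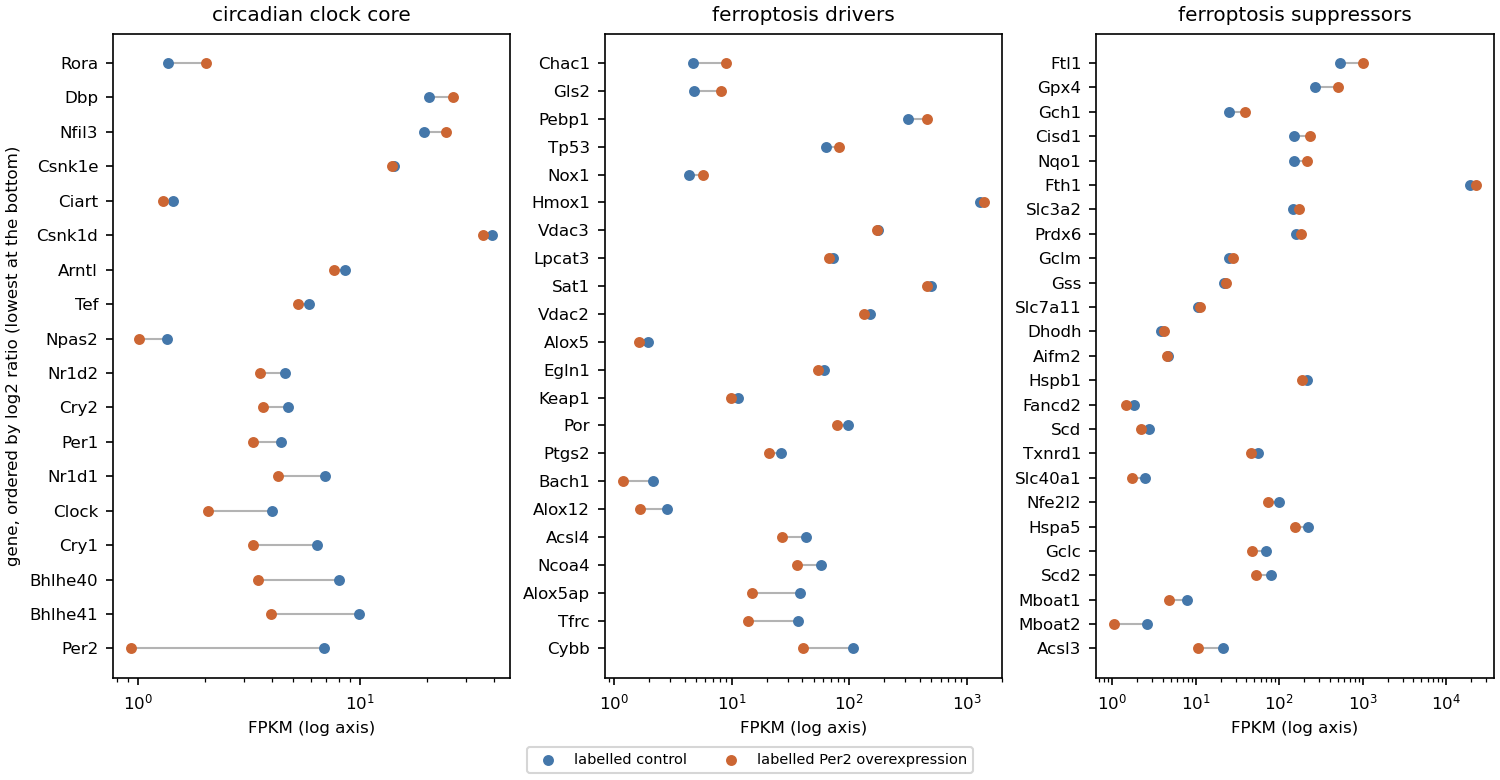
FPKM (log axis) of measured members (18 of 19 for the clock) of the circadian clock list and of the ferroptosis driver and suppressor lists, with 1 point for the control-labelled library (blue) and 1 for the library labelled Per2 overexpression (orange) per gene. Per2 has the lowest log2 ratio of its panel, -2.04, and Gpx4 and Ftl1 are at the top of the suppressor panel with 0.91 and 0.92.

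Genes that promote ferroptosis and genes that suppress it both went either way. Of 22 measured drivers, 16 had a log2 ratio below 0 and 6 above, 3 were at least 2-fold lower and 0 at least 2-fold higher. The 3 were Cybb (109 against 40.7 FPKM), which encodes a subunit of the phagocyte NADPH oxidase, Tfrc (36.7 against 13.8), the transferrin receptor for iron uptake, and Alox5ap (38.3 against 14.8), which assists 5-lipoxygenase. With the length trend removed, only Alox5ap was past 2-fold (-1.56), and Cybb (-0.99) and Tfrc (-0.94) were not. Of 21 drivers with a length, 10 then lay above 0 and 11 below. Acsl4, which loads polyunsaturated fatty acids onto coenzyme A, had 42.8 against 26.9 FPKM, and Ptgs2, a transcript often used as a marker of ferroptosis, had 26.3 against 20.9. The log2 ratio of Ptgs2 was -0.32, but 0.06 with the length trend removed, and that of Acsl4 was -0.65 and -0.23. Chac1, which degrades glutathione, had 4.67 against 9.05. Of 25 measured suppressors, 0 were past 2-fold by the rule on FPKM + 1. Gpx4, the peroxidase that detoxifies lipid peroxides, had 270 against 506 FPKM (log2 ratio 0.91), and Ftl1, the ferritin light chain, had 537 against 1019 (0.92). Acsl3 (21.2 against 10.7) and Mboat2 (2.63 against 1.05) were the lowest of the list. Slc7a11, the cystine importer, differed little (10.6 against 11.3 FPKM). So did Hmox1, the haem oxygenase, a member of the driver list (1289 against 1414). The directions of Slc7a11 and Hmox1 depended on the scaling and turned when the libraries were rescaled to TPM. With the length trend removed, Slc7a11 had a log2 ratio of 0.54, beside 0.52 for Gpx4 and 0.52 for Ftl1. Of 24 suppressors with a length, 15 then lay above 0 and 9 below. Fth1, the ferritin heavy chain, was among the most abundant transcripts, with 19283 against 22543 FPKM. Ferritin genes have processed copies in rodent genomes, so their values are uncertain.

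The median log2 ratio was -0.16 for drivers and -0.04 for suppressors. Among random lists matched on expression, 1778 of 10000 had a median as low as the drivers and 4585 as low as the suppressors. The numbers were 3121 and 8490 when length was matched too. The suppressors' median was 0.08 after median-of-ratios centring and -0.22 after TPM rescaling, so it has no direction independent of the scaling.

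Among 22 iron-handling genes, Tfrc, Heph (4.71 against 1.61 FPKM), a ferroxidase, and Tf (174 against 79.1), transferrin, were at least 2-fold lower, and Steap4 (9.52 against 20.9), a metalloreductase, was at least 2-fold higher. The list's median of -0.30 was matched by 213 of 10000 random lists, and by 1644 when length was matched, and it was -0.0032 with the length trend removed. Of 21 glutathione and thioredoxin genes, 15 were higher in the overexpression-labelled library. Mgst2, a microsomal glutathione transferase (113 against 315), was the only member past 2-fold, which it was not with the length trend removed (0.82), and Txn1 (thioredoxin) had 1607 against 2805 FPKM. Their median was 0.35, reached by 241 of 10000 random lists and by 937 when length was matched, and it was 0.19 with the length trend removed. The 17 measured NRF2 targets, the antioxidant response, had a median of 0.04 with 0 members past 2-fold, and this median was below 0 with no filter and after TPM rescaling. Nqo1 had 149 against 212 FPKM and Cat, catalase, had 39.9 against 28.2.

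Across all genes compared, 271 were at least 2-fold higher and 733 at least 2-fold lower in the overexpression-labelled library, of 12369. The median log2 ratio of all genes was -0.18. It was -0.37 after TPM rescaling, which gave 189 higher and 1400 lower genes, and -0.07 after median-of-ratios centring, which gave 406 and 548. The split between higher and lower genes thus depended on the scaling. With the pseudocount of 1, the highest log2 ratio among genes with a mean of at least 5 FPKM was that of Ccl20, a chemokine for CCR6-bearing lymphocytes, with 166 against 1602 FPKM (log2 ratio 3.26). Without a pseudocount Cfb, Ttr, Pla2g2a and Rpl35al1 had higher ratios than Ccl20. Pla2g2a, a secreted phospholipase, had 3.73 against 42.2, and Hp, haptoglobin, had 8.52 against 57.4. Cfb, complement factor B, had 0.899 against 12.5 FPKM at ENSRNOG00000000419, but a second row with the same symbol had 5.64 against 7.52, and the sum of both differed 3.06-fold. Ttr, transthyretin, had 3.53 against 42.3 FPKM, Mgp, matrix Gla protein, had 1052 against 5049, Npy, neuropeptide Y, had 1.55 against 12.6, and Mt1m, a metallothionein, had 3.18 against 17.7. Tbx1 (1.67 against 9.78) and Crct1 (47.1 against 183) were also among the 12. Rpl35a (1.86 against 16.4) and Rpl35al1 (1.95 against 19.5) completed them. They are near-identical copies whose reads could be split, so their values are uncertain.

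The 12 lowest ratios were led by Cdkn2b, an inhibitor of cyclin-dependent kinases, with 18.04 against 0.960 FPKM (log2 ratio -3.28). Cd4 had 24.9 against 2.56 FPKM and Stat6, the transcription factor of interleukin-4 signalling, had 24.0 against 3.69. Thbs1, thrombospondin 1, had 54.7 against 8.64, Selenop, a selenium carrier protein, had 86.3 against 16.6, and Fcrl2 had 58.0 against 8.97. C1qb, a chain of complement C1q, had 116 against 22.3. Rgs18 (14.7 against 1.97), Atp1b2 (14.9 against 2.02), Epb41l2 (14.9 against 2.32) and Myh9, the heavy chain of non-muscle myosin (14.8 against 2.29), followed. Hmg1l1, of the high-mobility group family, had 10.5 against 0.706 FPKM, and its value is uncertain because family members share sequence.

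The libraries differed systematically with transcript length, and this bears on every ratio above and below. Across 10161 genes with a length, Spearman's rho between the log2 ratio and length was -0.50. The median log2 ratio was 0.43 in the 1017 genes with the shortest transcripts (204 to 1271 nt) and -0.47 in the 1016 genes with the longest (6239 to 23495 nt). A length was at hand for 120 of the 271 genes at least 2-fold higher, with a median of 1107 nt. It was at hand for 540 of the 733 genes at least 2-fold lower, with a median of 4174 nt. Genes without a length could not be adjusted. Among genes with one, 137 were at least 2-fold higher and 245 at least 2-fold lower once the length trend was removed. The removal also recentres the ratios, so not every change in these calls is due to length. Of the 540 lower genes with a length, 217 stayed past 2-fold, and of the 120 higher genes, 69 did. Per2 stayed at -1.60, C1qb at -2.66, Cdkn2b at -3.45, Ccl20 at 3.11 and Hp at 2.43. Calls were fewer in several lists: among members with a length, 0 iron-handling, 3 homeostatic, 3 complement, 4 alternative activation, 2 astrocyte, 1 oligodendrocyte, 1 precursor and 1 lipid gene were then at least 2-fold lower, and 1 chemokine was at least 2-fold higher. The counts for damage-associated (3) and monocyte (4) genes were equal before and after, but the members counted were not the same in either list. In the damage-associated list Lpl (-0.83) left the count and Apoe (-1.12) entered it. Of 72 genes taken by the naming rule that were past 2-fold and had a length, 25 were then under it, among them Csf2, Nfkbiz, Abcg1, Heph, Lpl, Pfkfb3, Col6a1, Cxcl1, Rplp2 and Fos.

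**Figure D2:**
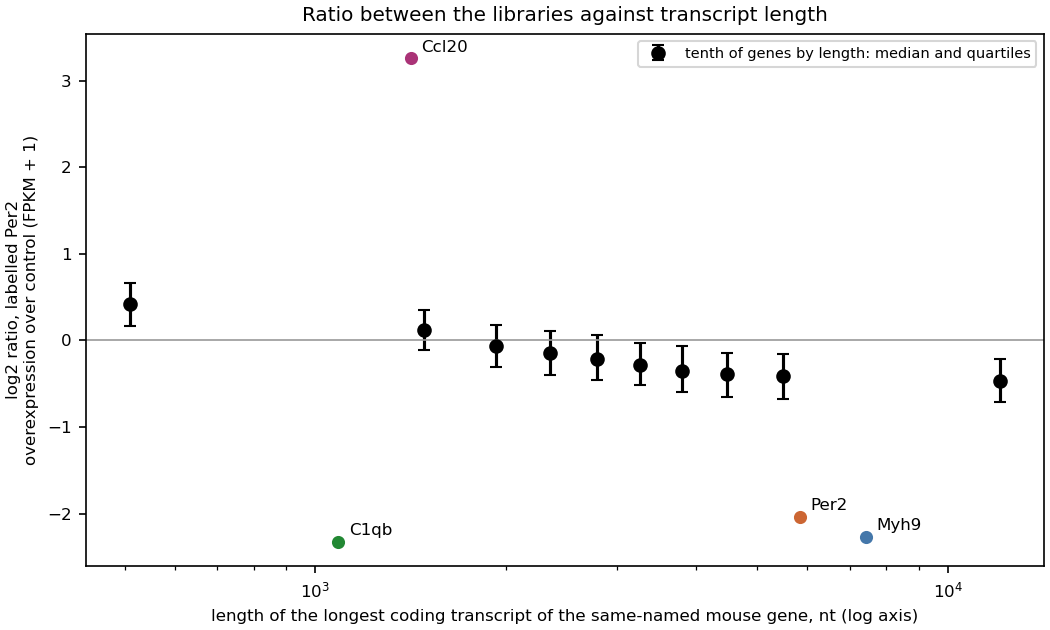
Median log2 ratio between the libraries (FPKM + 1; vertical axis) in 10 classes of 10161 genes by the length in nt of the same-named mouse transcript (log axis), with bars for the quartiles over genes, drawn at the geometric mean of the class limits, and coloured points for Per2, C1qb, Ccl20 and Myh9. The medians run from 0.43 in the shortest class to -0.47 in the longest, and Per2 lies at -2.04, below the quartiles of its length.

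Most measured homeostatic microglia markers and most complement and phagocytosis genes had lower values in the overexpression-labelled library. Of 16 homeostatic markers, 14 had a log2 ratio below 0 and 2 above, and 5 were at least 2-fold lower and 0 at least 2-fold higher. They were Gpr34 (11.5 against 1.73 FPKM), C1qa (257 against 71.6), Selplg (39.7 against 14.9), Tgfbr1 (11.3 against 3.65) and Csf1r, the receptor for the growth factor that sustains microglia (51.5 against 21.7). With the length trend removed, Tgfbr1 (-0.97) and Csf1r (-0.81) were under 2-fold. Aif1, which encodes IBA1, had 579 against 491 FPKM and Tmem119 had 21.5 against 27.5. P2ry12 was under the filter with 0.650 against 0.0802 FPKM, and Cx3cr1 was listed at 0 in both libraries. The list's median was -0.69. None (0) of 10000 random lists matched on expression had a median as low, and 1 did when length was matched too.

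Of 22 complement and phagocytosis genes, 16 had a log2 ratio below 0 and 6 above. Of these, 4 were at least 2-fold lower, with C1qc (99.0 against 26.6 FPKM) beside C1qa and C1qb, and 1, Cfb, was at least 2-fold higher. Their median was -0.53, with 0 random lists as low under either matching. The alternative activation and repair list held 8 of 16 members at least 2-fold lower, among them Igf1 (23.5 against 5.17), Stab1 (4.39 against 0.388), Cd163 (3.74 against 0.550) and Mrc1, the mannose receptor (114 against 39.3). Its median of -0.86 was reached by 0 random lists under either matching, but it was -0.37 with a pseudocount of 5, -0.48 with no filter and -0.35 with a mean of at least 5 FPKM. All 25 lysosomal genes lay within 2-fold, but 21 were lower, with a median of -0.40 (-0.20 with the length trend removed) and 0 random lists as low under either matching. Psap, prosaposin, had 1591 against 815 FPKM and Ctss, cathepsin S, had 567 against 342. Damage-associated microglia genes had a median of -0.30, with 3 of 21 members at least 2-fold lower (Igf1, Lpl and Clec7a), and 22 length-matched random lists as low. Apoe had 5364 against 2762 FPKM and Gpnmb had 1854 against 938. Monocyte and peripheral macrophage markers had a median of -0.37 (-0.72 with the length trend removed), and 4 of 13 were at least 2-fold lower, including Clec4a3 (206 against 82.9). The medians of these lists stayed below 0 under each alternative scaling, filter and pseudocount run. Scaling and pseudocount could hardly have turned medians of this size. The lists share members with each other and with the homeostatic list, such as C1qa, Igf1, Mrc1 and Cd163, so their shifts are not independent.

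Most markers of other glia were also lower. All 11 measured astrocyte markers were below a log2 ratio of 0 and 5 were at least 2-fold lower, including Gfap (56.4 against 17.8 FPKM), Aldoc (53.01 against 17.8), Fgfr3 (9.70 against 3.55) and Gja1 (163 against 74.9). With the length trend removed, Fgfr3 (-0.86) and Gja1 (-0.86) were under 2-fold. Their median was -0.87, with 2 length-matched random lists of 10000 as low. The 7 oligodendrocyte markers had a median of -0.91 (-0.44 with a pseudocount of 5 and -0.52 with no filter), with Sox10 at 2.88 against 0.791 and Olig1 at 10.1 against 3.86. The 6 precursor markers, of which Olig1, Olig2 and Sox10 are shared with the oligodendrocyte list, had a median of -1.08, which was -0.50 with a pseudocount of 5. Of these 6, Pdgfra was higher (7.40 against 9.72, log2 ratio 0.35) and is named after its value was seen. Fibroblast and pericyte markers showed no such shift as a list (median -0.19, above 0 with the length trend removed, 2769 length-matched random lists as low), although Col6a1 had 8.93 against 3.55 FPKM. The 12 measured members of that list had a median of 96.9 FPKM in the control-labelled library and 70.9 in the other. Fewer than 5 neuron, endothelial, neutrophil and lymphocyte markers were measured. The neuronal genes were Stmn2 (27.6 against 16.0 FPKM), Tubb3 (9.44 against 10.02), Syt1 (1.71 against 0.561) and Gad1 (1.36 against 0.719). The endothelial genes were Esam (54.2 against 59.2), Flt1 (3.57 against 2.86) and Tie1 (1.78 against 1.09). Of the neutrophil genes, S100a8 had 677 against 753, S100a9 had 1.79 against 0.688, Camp had 1.64 against 1.73 and Csf3r had 1.38 against 0.821, and the log2 ratio of S100a8 was below 0 with the length trend removed (-0.61). The lymphocyte genes were Cd4, Cd8a (16.0 against 2.81) and Lck (2.67 against 2.28). Values from whole cultures cannot tell a change within microglia from a difference in the cell types present, and this was not tested.

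Most chemokine transcripts had higher values in the overexpression-labelled library, few of them by 2-fold. Of 18 measured chemokines, 15 had a log2 ratio above 0, Ccl20 and Cxcl1 (823 against 1709 FPKM) were at least 2-fold higher, and Cxcl13, a B-cell attractant, was at least 2-fold lower (12.9 against 3.23). The median was 0.62, reached by 5 of 10000 random lists and by 8 when length was matched. The median stayed above 0 under each alternative run, although scaling and pseudocount could hardly have turned a median of this size. With the length trend removed it was 0.28, with 13 members above 0 and 5 below. Pro-inflammatory cytokines and mediators as a list had a median of 0.06, which was below 0 after TPM rescaling, with 8 members above 0 and 8 below. Within it Il6 (21.1 against 47.8) and Csf2 (9.33 against 19.8) were at least 2-fold higher, and Csf3 had 82.7 against 162 and Ptges, prostaglandin E synthase, 141 against 249. The lowest log2 ratio in the list was -0.80. NF-kB feedback genes had a median of -0.12, above 0 with the length trend removed, with Tnfaip3, which encodes the inhibitor A20, at 5.73 against 1.18 FPKM and Nfkbiz at 19.0 against 7.36. Of 28 interferon-response genes, Oas1a (13.5 against 32.7), Isg15 (52.98 against 121) and Ifi27 (604 against 1334) were at least 2-fold higher and Ddx58, which encodes RIG-I, was at least 2-fold lower (4.71 against 1.02). With the length trend removed, Isg15 (0.65) and Ifi27 (0.75) were under 2-fold. Their median of 0.14 was reached by 62 random lists, or 11 when length was matched, and was below 0 after TPM rescaling and 0.22 with the length trend removed. Antigen presentation genes had a median of 0.06, below 0 with no filter and after TPM rescaling, with RT1-CE1, a class I gene of a family with shared reads, at 11.8 against 32.4. Of 15 measured members of that list, 8 had a log2 ratio above 0 and 7 below, down to -0.82.

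**Figure D3:**
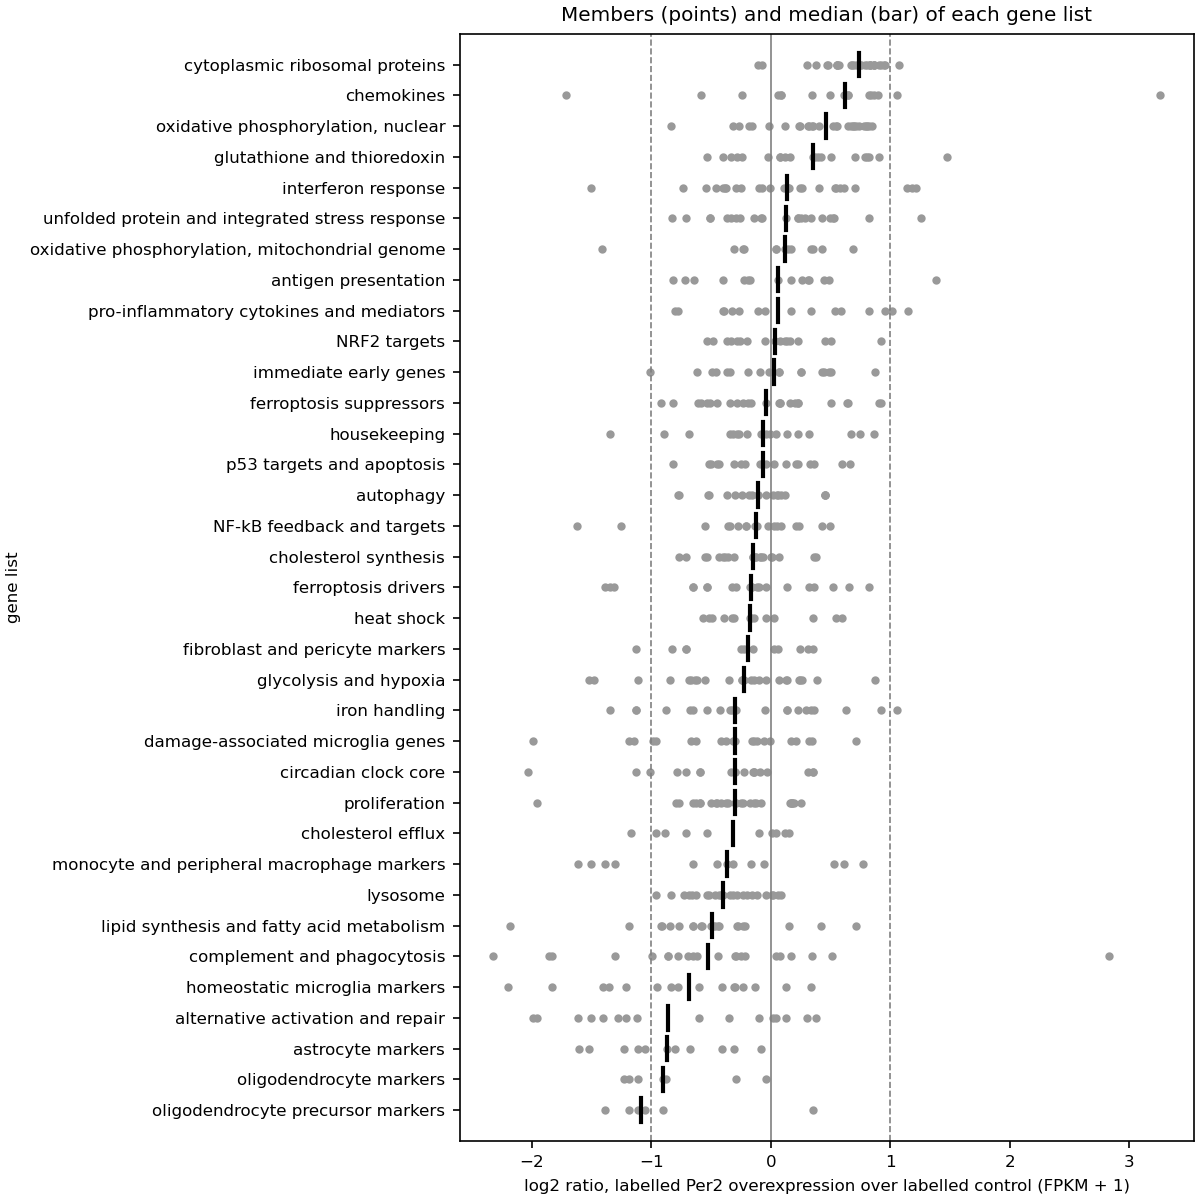
Log2 ratio (FPKM + 1) of the measured members (grey points) and the median (black bar) of each gene list with at least 5 measured members, ordered by median, with dashed lines at the 2-fold limits of -1 and 1. Ribosomal protein genes (median 0.74) and chemokines (0.62) lie at the top, and oligodendrocyte precursor (-1.08), oligodendrocyte (-0.91) and astrocyte (-0.87) markers lie at the bottom.

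Genes of lipid metabolism were lower as a list. Of 22 genes of lipid synthesis and fatty acid metabolism, 19 had a log2 ratio below 0. Elovl5, an elongase of polyunsaturated fatty acids (25.4 against 4.82 FPKM), and Lpl, lipoprotein lipase (85.0 against 36.7), were at least 2-fold lower, and Fads1, a desaturase of the same pathway, had 19.6 against 9.93. The median was -0.49, with 3 random lists as low and 72 when length was matched, and it was -0.23 with the length trend removed. Cholesterol synthesis genes did not stand apart (median -0.15, or -0.016 with the length trend removed, with 7811 length-matched random lists as low). Sqle, a member of that list, had 60.0 against 40.6. Abcg1, a cholesterol exporter, had 9.51 against 3.67, and the median of the efflux list was -0.32 with 2415 length-matched random lists as low, and -0.041 with the length trend removed.

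Most ribosomal protein genes and nuclear genes of oxidative phosphorylation had higher values in the overexpression-labelled library. Of 30 ribosomal protein genes, 28 had a log2 ratio above 0, with a median of 0.74, and Rplp2 had 320 against 676 FPKM. Over a wider set of 91 ribosomal protein genes, the share of summed FPKM was 7.91% in the control-labelled library and 11.8% in the other. No expression-matched random list (0 of 10000) reached their median, and 1 did when length was matched. With the length trend removed the median was 0.34. Of 28 nuclear genes of oxidative phosphorylation, 22 had a log2 ratio above 0 and 6 below, with a median of 0.46 and 0 members past 2-fold, and Ndufa4 had 244 against 431. Their median was reached by 177 random lists, and by 382 when length was matched, and it was 0.17 with the length trend removed. Transcripts of the mitochondrial genome took 8.78% and 8.36% of summed FPKM. As a list they had a median of 0.12, which was below 0 after TPM rescaling and with the length trend removed, and Mt-nd4l had 837 against 313 FPKM. Of 10000 random lists, 1339 had a median as low, and 18 when length was matched. Housekeeping genes, which serve as a gauge of the spread, had a median of -0.06 that was above 0 after median-of-ratios centring. Single members ranged from -1.34 to 0.87, with Actb at 3081 against 1659 FPKM and Ppia at 187 against 342. The lowest was Tfrc, named above among drivers and iron-handling genes and the only housekeeping member past 2-fold.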

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

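Removal of the length trend and restriction to annotated genes were chosen after the data had been seen, and the other alternatives before. The count of genes at least 2-fold higher (271) was 413 with a pseudocount of 0.1 and 120 with a pseudocount of 5. The count of genes at least 2-fold lower (733) was 1304 and 164 under the same settings, 366 with a mean of at least 5 FPKM and 1400 after TPM rescaling. Among the 10161 genes with a length, removing the length trend took the higher count from 120 to 137 and the lower count from 540 to 245. That step also recentres the ratios, so these changes are not due to length alone. Median-of-ratios centring by itself, over all 12369 genes, gave 406 higher and 548 lower. Under the remaining settings the counts stayed within 1.5 times. Per2 kept its direction throughout, which pseudocount, TPM rescaling and centring could not have turned for a ratio of its size. Its log2 ratios were -2.77 and -1.01 with pseudocounts of 0.1 and 5 and -2.37 after TPM rescaling. They were -1.92 after median-of-ratios centring and -1.60 with the length trend removed.

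The median of the clock list (-0.30) was -0.37 and -0.17 with pseudocounts of 0.1 and 5, -0.26 with no filter, -0.14 with a mean of at least 5 FPKM, -0.49 after TPM rescaling, -0.19 after centring and 0.061 with the length trend removed. For ferroptosis drivers (-0.16) the values in that order were -0.18, -0.14, -0.15, -0.15, -0.36, -0.049 and -0.097. For suppressors (-0.04) they were -0.0215 with a pseudocount of 5, 0.0779 with a mean of at least 5 FPKM, -0.22 after TPM rescaling, 0.0782 after centring and 0.14 with the length trend removed. Of 78 named genes past 2-fold, 0 turned direction under any alternative run. A pseudocount cannot turn the sign of a ratio, and TPM rescaling and centring shift ratios by far less than the 2-fold limit. For these genes only the length adjustment could have turned a direction. Of these, 22 lay under 2-fold with a pseudocount of 5, 7 after TPM rescaling, 5 after centring, and 25 of the 72 with a length once the length trend was removed. Over all named genes, 15 of 174 turned sign with the length trend removed, 6 of 186 after TPM rescaling and 2 of 186 after centring. Of 35 list medians, 7 turned sign after TPM rescaling, 4 after centring, 3 with no filter and 7 with the length trend removed, as did 1 of the 33 with a value at a mean of at least 5 FPKM. The cause of these differences was not tested. Leaving out a library was not possible with 1 per group, and depth is unknown, so the counting error of low values such as Per2 cannot be given.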

Other observations

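Of 27 proliferation genes, 1 was at least 2-fold lower by the rule on FPKM + 1. This was Rrm2, the small subunit of ribonucleotide reductase (22.0 against 4.92 FPKM, control-labelled value first). Mki67 had 2.70 against 1.13, a 2.38-fold difference that the pseudocount left under the limit (log2 ratio -0.79). The list's median log2 ratio was -0.30, with 3696 of 10000 length-matched random lists as low, and -0.052 with the length trend removed. In the glycolysis and hypoxia list Hk1, hexokinase 1 (18.9 against 6.13), Aldoc and Pfkfb3 (45.1 against 20.3) were at least 2-fold lower, and its median of -0.23 was reached by 1596 length-matched lists and was -0.14 with the length trend removed. The unfolded protein and integrated stress response list had a median of 0.12, below 0 after TPM rescaling, and Trib3, a pseudokinase of that response, had 4.42 against 11.98 FPKM, while 266 length-matched lists had a median as high. The heat shock, autophagy, p53 and immediate early lists had medians of -0.17, -0.11, -0.07 and 0.03. With the length trend removed the heat shock median was -0.031. The autophagy and p53 medians were above 0 after median-of-ratios centring and with the length trend removed, and the immediate early median was below 0 with no filter and after TPM rescaling. Of those, Fos was the only member past 2-fold (6.98 against 2.97).

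The tests below, apart from those on ribosomal and respiratory genes and on GC content, were chosen after the results they bear on had been seen. The first pattern is that Per2 was lower in the library labelled Per2 overexpression. The length trend does not account for all of it, since the length-adjusted log2 ratio of Per2 was still -1.60. If the labels had been exchanged, 10 other E-box clock genes that PER2 represses might be higher in the library labelled overexpression, and if the vector's transcript was not counted while PER2 protein acted, they might be lower. Their median was -0.32 before and 0.00 after length adjustment, the latter at percentile 55.7 of matched random lists with 5 above and 5 below 0. Neither expectation was met, so exchanged labels and an uncounted vector transcript cannot be told apart for Per2. They are not the only possible explanations, and others beyond the length trend were not tested. The sequence of the vector and the reads were not analysed here.

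The second pattern is that shorter transcripts were higher in the overexpression-labelled library. Ribosomal protein and respiratory chain genes alone are not its source, since rho was -0.48 without 263 such genes. GC content of the mouse transcript alone does not account for it, since the partial rho with length given GC was -0.46. The log2 ratio had a rho of 0.26 with GC, and 0.15 given length, so a part for GC stays open. The trend was present in each of 3 classes of genes by expression, without the same 263 genes, with the weakest rho at -0.30, but any cause of the trend predicts this. A difference in RNA fragmentation or size selection and an effect of the vector itself on long mRNAs cannot be told apart, because the overall rho of -0.50 comes from the only pair of libraries. Under either, lists of long genes that are low, such as clock genes, and lists of short genes that are high, such as oxidative phosphorylation, may owe part of their raw medians to length, whereas complement genes had a median of -0.48 with the length trend removed.

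The third pattern is that Cd4 (24.9 against 2.56 FPKM) and Cd8a (16.0 against 2.81) were present while the T-cell receptor complex genes were close to 0, although Lck stood at 2.67 against 2.28. T lymphocytes are not a likely source, because the highest of Cd3d, Cd3e, Cd3g and Cd2 stood at 0.0117 of the Cd4 value in the control-labelled library. Macrophages and microglia of rats carry CD4, which those of mice mostly lack, so rat cells are a candidate explanation for Cd4 at 24.9 FPKM, along with the rat gene identifiers. This was not tested on reads, and a cross-species alignment of mouse reads stays open.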
